A study of Mus musculus with 15 samples.

How the data were processed

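RNA was measured in livers of male C57BL/6J mice after 9 months on a diet with 10%, 60% or 89.9% fat, from 15 libraries with 5 per diet. Per the labels' protocols, poly(A) RNA was selected and made into libraries with a kit that keeps strand. The deposited values are whole-number read counts per Ensembl gene, 1 column per library, for 56980 gene IDs. The submitters' processing notes name cutadapt 1.16, STAR 2.7.9a, featureCounts 1.6 and DESeq2 1.36.0 and the mouse build GRCm39, with no order or role. The annotation release, the strand setting of the counting and the handling of reads that match several genes are not given in the sources used here. Values of overlapping and antisense genes and of near-identical gene copies, such as the Cyp4a, Cyp2b, Cyp2c, Saa, Gsta and Mup families, are therefore uncertain. Gene symbols came from a mouse annotation of an earlier build, used for names only, and matched 91.39% of all IDs and 98.17% of the 14627 tested; no coordinates are given.

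Control replicate 1 was left out of all comparisons, because the submitters excluded it as contaminated, and was described on its own. Total counts of the 14 libraries used ran from 16329425 to 25349148. Genes were kept with edgeR 4.0.16's filterByExpr (minimum count 10, minimum total 15), scaled with TMM, whose factors ran from 0.886 to 1.215, and tested in 1 fit over the 3 diets with estimateDisp, robust glmQLFit and the two-sided glmQLFTest in R 4.3.3. The biological coefficient of variation was 0.25. P-values were adjusted with the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. Log2 fold changes come from this model, and CPM values are scaled by TMM. The SE printed with a log2 fold change is its absolute value divided by the square root of the test's F statistic. A group with 0 counts was set to a floor of 3 counts over the group.

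Before the data were examined, the design, the alternatives and the genes to name were fixed. For each comparison the rule took the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 1 CPM, a symbol that is neither a predicted-gene or clone name nor a pseudogene, and no overlap between both groups. It also took up to 3 members of each list with the smallest adjusted p past the threshold, or else the tested member with the highest mean CPM, and 18 genes whatever their result. The text prints part of these. Some members of the lists are not reported here by name.

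The 47 lists were also fixed before the data were examined: ketogenesis and ketone export, PPAR-alpha targets and fatty acid oxidation, de novo lipogenesis, cholesterol synthesis and SREBP2 targets, bile acid synthesis and transport, cholesterol efflux and lipoproteins, lipid droplets and lipid uptake, gluconeogenesis and glycogen, glycolysis and fructose metabolism, amino acid breakdown and urea cycle, ATF4 amino acid response, ER chaperones and unfolded protein response, NRF2 and oxidative stress, xenobiotic CYPs and CAR/PXR targets, male-biased liver genes, female-biased liver genes, circadian clock, insulin-FOXO1 targets, hepatokines and endocrine factors, mitochondrial OXPHOS subunits (nuclear), acute phase proteins, inflammatory cytokines and chemokines, interferon response, fibrosis and extracellular matrix, cell cycle, oncofetal and hepatocyte injury genes, hepatocyte markers, resident Kupffer cell markers, monocyte-derived and lipid-associated macrophage markers, neutrophil markers, T and NK cell markers, B and plasma cell markers, dendritic cell markers, stellate cell and fibroblast markers, liver sinusoidal endothelial cell markers, cholangiocyte markers, erythroid markers, adipocyte markers, pancreatic acinar markers, pancreatic islet markers, intestinal and gallbladder epithelium markers, skeletal muscle markers, mesothelium markers, kidney epithelium markers, pericentral hepatocyte genes, periportal hepatocyte genes and mitochondrially encoded mRNAs. Lists with at least 3 tested members, 45 of them, were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, again with the correlation estimated for each list, and with fry, adjusted over the 135 tests of the 3 comparisons. Only de novo lipogenesis and glycolysis, both in ketogenic against high-fat livers, held with the estimated correlation. Fry tests whether the genes of a list move one way on balance, and does not compare the list with other genes. Marker lists were read as transcript levels, never as numbers of cells.

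The tests were tried on simulated counts with 200 genes changed by 1.5, 2 or 4-fold. For high-fat against control, edgeR recovered 11.9%, 58.2% and 93.9% of these over 14400 genes, with 3 of 119 calls false; for ketogenic against control 19.4%, 73.1% and 93.9% over 14394 genes, with 7 of 136 false; and for ketogenic against high-fat 41.8%, 61.2% and 95.5% over 14400 genes, with 6 of 145 false. DESeq2 made 26 of 166, 28 of 179 and 30 of 185 false calls, and limma-voom 0 of 115, 7 of 134 and 7 of 142. A list of changed genes was called in each simulated comparison with both settings of camera, and 0 of 45 unchanged lists were. The simulated genes were drawn independently of each other and the unchanged lists at random. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes at the preset correlation.

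The alternatives were DESeq2 size factors or library totals as scaling, DESeq2 1.42.0 and limma-voom with quality weights as tools, no filter or a stricter one (1 CPM in 4 libraries), a fit of only the groups compared, control replicate 1 put back, the replicate number as a block, the library number set (1 to 9 against 13 to 25 in the titles) as a covariate, stricter thresholds, the 20 most abundant genes left out, and each library left out in turn. Leaving out pairs of libraries was added after the data were seen, and fry was listed then as an alternative to camera. For each comparison, 100 splits of its libraries into groups of the same sizes were drawn, the real one included.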

Results

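Liver RNA of male C57BL/6J mice was sequenced after 9 months on 1 of 3 diets begun at 15 weeks of age, to show how a ketogenic diet changes gene expression in the liver. The diets were a control diet (10% fat), a high-fat diet (60% fat) and a ketogenic diet (89.9% fat). Each diet had 5 libraries, and control replicate 1 was left out of every comparison because the submitters state that it was contaminated, which left 4 control, 5 high-fat and 5 ketogenic libraries. Total counts per library ran from 16329425 to 25349148 over these 14, and 14627 genes were tested. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples. No library pair held identical values, and Spearman correlations between libraries ran from 0.928 to 0.990 over the 105 pairs. Levels are CPM (counts scaled to a common library total) after TMM scaling, given as mean ± SD with n = 4 control libraries and n = 5 libraries of each fat-rich diet. Log2 fold changes are given with an SE derived from the F statistic of the test.

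Controls lay apart from both fat-rich diets on the first principal component, which held 34.4% of the variance, and the second, with 16.5%, placed 4 of the 5 ketogenic libraries apart from the high-fat ones. Ketogenic replicate 5 was the exception: on the second component it lay at 26.2, above all high-fat libraries, while the other ketogenic libraries lay between -51.9 and -23.3. High-fat replicate 1 lay at -15.7 on the first component, nearer to the controls than the other high-fat libraries, which lay between 17.6 and 34.6. Transcripts of pancreatic acinar cells, from an organ beside the liver, made up 1.897% of the counts of the excluded control replicate 1 (95% Clopper-Pearson interval 1.892 to 1.903) and 0.00265% to 0.199% in the other controls, 0.0126% to 0.0862% in high-fat and 0.000853% to 0.0425% in ketogenic libraries. Counting intervals and floors given here cover counting error only.

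**Figure D1:**
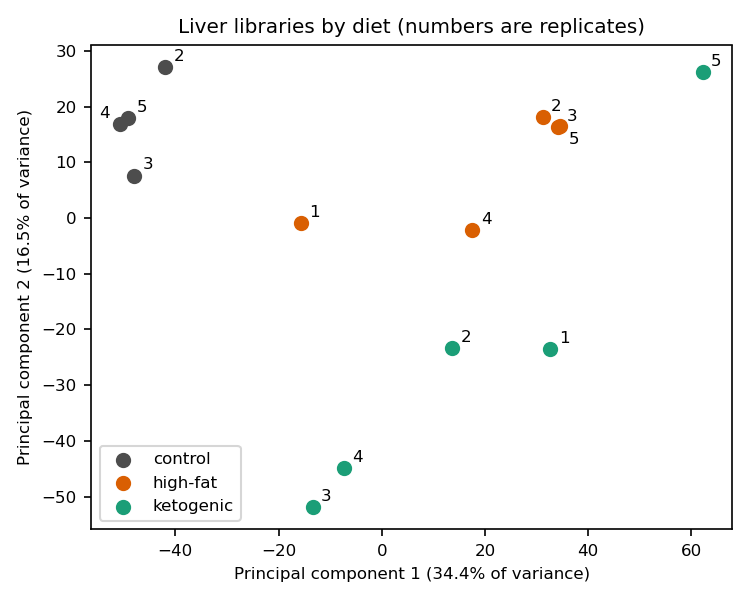
Principal components of log2 CPM of the 14 libraries used; each point is a library, coloured by diet and numbered by replicate, and the axes give the share of variance. The 4 control libraries lie on the left, and ketogenic replicate 5 lies at 62.2 on the first and 26.2 on the second component, away from the other 4 ketogenic libraries.

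High-fat and control livers were compared first. After 9 months on the 60% fat diet, 31 of 36 PPAR-alpha target and fatty acid oxidation genes, 4 of 6 genes of ketone production and 18 of 24 of lipid droplets and uptake were higher than in controls. Some genes of liver injury and matrix were also higher, while 17 of 27 endoplasmic reticulum chaperone genes were lower. These list calls are lost with an estimated correlation (adjusted p from 0.0515 to 0.580). Cidec, a lipid droplet protein, went from 2.99 ± 1.53 to 96.8 ± 38.9 CPM, and Cd36, a fatty acid transporter, from 28.5 ± 7.07 to 248 ± 72.9 CPM. Hyou1, an endoplasmic reticulum chaperone, went from 348 ± 69.2 to 113 ± 25.7 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1016 genes rose and 733 fell, 478 and 145 of them by at least 2-fold. With library totals in place of TMM the split was 1302 higher and 420 lower, because that scaling shifts the median gene by 0.127 on the log2 scale. Over all tested genes, 16.2% had no overlap between the CPM values of both groups, where chance gives 1.59%. The count fell to 1077 without control replicate 3, 934 without control replicate 4, 1132 without control replicate 5 and 1131 without high-fat replicate 4.

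Among the genes with the largest changes after the high-fat diet were cytochrome P450 enzymes and a lipid droplet gene. Cyp2b13 had 0 counts in the 4 control libraries and 1391 counts (13.7 ± 13.7 CPM) in the high-fat ones, at least 344-fold higher against a floor of 3 counts over the control group (adjusted p = 0.0273). Sprr1a, an epithelial envelope protein, was likewise at 0 in controls and reached 1.99 ± 1.98 CPM, at least 49.7-fold higher (adjusted p = 0.0196). Mab21l3 had 1 count in controls and 198 after the high-fat diet, a ratio of 147 with a 95% counting interval of 26.1 to 5830. Cyp2b9 rose from 0.632 ± 0.547 to 111 ± 59.1 CPM (log2 fold change 7.44 ± 0.87 (SE), adjusted p = 0.000343). Cyp4a14, a fatty acid hydroxylase, rose from 2.74 ± 1.89 to 429 ± 319.8 CPM (log2 fold change 7.30 ± 0.90 (SE), adjusted p = 0.000418), and Cidea, a lipid droplet protein of brown fat, from 0.581 ± 0.403 to 44.0 ± 27.5 CPM (log2 fold change 6.23 ± 0.79 (SE), adjusted p = 0.000457). Among genes that fell, Moxd1 went from 39.5 ± 42.3 to 0.127 ± 0.284 CPM (log2 fold change -8.39 ± 1.35 (SE), adjusted p = 0.00232). Adgrf1, an adhesion receptor, fell from 9.70 ± 2.19 to 0.181 ± 0.212 CPM (log2 fold change -5.76 ± 0.55 (SE), adjusted p = 1.86e-05). Tff3, a secreted trefoil peptide, fell by 4.43 on the log2 scale (adjusted p = 0.00107). The acetyltransferase gene Nat8f7 had a log2 fold change of -3.06 ± 0.55 (adjusted p = 0.00238) and the cell adhesion gene Cadm4 of -3.03 ± 0.63 (adjusted p = 0.00798). Pnpla3, a lipid droplet hydrolase, had a log2 fold change of -3.10 ± 0.93 (adjusted p = 0.0481). Its call was lost without any 1 of 8 libraries, all but high-fat replicate 1, with adjusted p from 0.0565 to 0.109, and with library totals (adjusted p = 0.0629) or the library number set as a covariate (adjusted p = 0.0617). The call on Cyp2b13 was lost without high-fat replicate 4 or control replicate 3, 4 or 5 (adjusted p from 0.0503 to 0.0647). With the replicate number as a block the calls on Pnpla3 and Cyp2b13 were also lost (adjusted p = 0.0906 and 0.0702). Leaving out high-fat replicate 1 moved the log2 fold change of Adgrf1 to -6.57, and Moxd1, then at 0 counts in high-fat libraries, was at least 1100-fold lower by the floor of 3 counts. Leaving out control replicate 4 moved Moxd1 to -7.71 and leaving out control replicate 2 moved Tff3 to -3.65. Without high-fat replicate 5 the bound was 213-fold for Cyp2b13 and 29.1-fold for Sprr1a. Mab21l3 was at 0 in controls without control replicate 5, at least 37.4-fold higher after the high-fat diet.

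Genes of fat oxidation and storage rose as groups. Of the 36 targets of the nuclear receptor PPAR-alpha and fatty acid oxidation genes, 31 rose and 0 fell (32 and 0 when adjusted over the list alone; camera adjusted p = 1.87e-29, against adjusted p = 0.0515 with an estimated correlation). Among them were Vnn1, a pantetheinase (3.59 ± 0.31 (adjusted p = 1.46e-05)), Acaa1b, a peroxisomal thiolase (2.03 ± 0.19 (adjusted p = 1.55e-05)), and Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria (0.74 ± 0.19 (adjusted p = 0.0188)). In the list of ketogenesis and ketone export, 4 of 6 rose (5 when adjusted over the list alone; camera adjusted p = 0.000356, against adjusted p = 0.205 with an estimated correlation). Among them was the thiolase gene Acat1 (0.89 ± 0.16 (adjusted p = 0.00272)). Of the 24 genes of lipid droplets and lipid uptake, 18 rose and 0 fell (20 and 1 when adjusted over the list alone; camera adjusted p = 1.33e-17, against adjusted p = 0.0515 with an estimated correlation). On the log2 scale Cidec rose by 5.01 ± 0.42 (adjusted p = 1.46e-05), Cd36 by 3.12 ± 0.29 (adjusted p = 1.86e-05), the droplet coat gene Plin2 by 1.85 ± 0.22 (adjusted p = 0.000110) and Mogat1, a monoacylglycerol acyltransferase, by 5.18 ± 0.39 (adjusted p = 7.82e-06). Pdk4, a kinase that turns off pyruvate dehydrogenase, rose by 1.82 ± 0.45 (adjusted p = 0.0194), and the hormone gene Fgf21 by 2.46 ± 0.37 (adjusted p = 0.000669). Without control replicate 4 the call on Cpt1a was lost (adjusted p = 0.0572), and that on Pdk4 was lost without control replicate 3 or 4 (adjusted p = 0.0609 and 0.0647).

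Lipid synthesis moved in both directions. In the 25 genes of de novo lipogenesis, 2 rose and 6 fell (3 and 14 when adjusted over the list alone; camera adjusted p = 6.85e-05, against adjusted p = 0.448 with an estimated correlation). Pklr, the liver pyruvate kinase, fell (-1.29 ± 0.18 (adjusted p = 0.000383)). Srebf1, the transcription factor gene of the lipogenic program (-1.29 ± 0.31 (adjusted p = 0.0146)), fell too, a call lost without control replicate 4 (adjusted p = 0.0520). The desaturase gene Fads2 rose (1.07 ± 0.17 (adjusted p = 0.00111)). Fatty acid synthase (Fasn) at 1555 ± 877 against 4032 ± 1114 CPM (-1.37 ± 0.51 (adjusted p = 0.0969)) and the stearoyl-CoA desaturase gene Scd1 at 10871 ± 3994 against 14652 ± 4549.6 CPM (-0.43 ± 1.82 (adjusted p = 0.908)) did not pass. Of 20 genes of glycolysis and fructose metabolism, 4 fell and 0 rose (8 and 4 when adjusted over the list alone). Gpi1, the glucose phosphate isomerase, was at -0.71 ± 0.10 (adjusted p = 0.000366). Of 16 of gluconeogenesis and glycogen, 3 rose and 4 fell (4 and 4 when adjusted over the list alone); Pck1, the gluconeogenic carboxykinase, did not pass (0.40 ± 0.37 (adjusted p = 0.514)). Of 37 genes of amino acid breakdown and the urea cycle, 2 rose and 1 fell, with the same counts adjusted over the list alone, and the 1 was Cps1, the entry enzyme of the urea cycle (-0.93 ± 0.21 (adjusted p = 0.0110)). Cholesterol synthesis and SREBP2 targets held 2 higher and 2 lower genes of 25 (2 and 3 when adjusted over the list alone). Bile acid synthesis and transport held 5 higher and 2 lower of 24 (5 and 4), with the transporter genes Abcc3 (1.88 ± 0.30 (adjusted p = 0.00109)) and Abcb4 (1.05 ± 0.17 (adjusted p = 0.000988)) higher. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass, at -0.59 ± 0.49 (adjusted p = 0.474). Cholesterol efflux and lipoproteins held 1 higher and 1 lower of 24, the same counts adjusted over the list alone, with the apolipoprotein gene Apoa4 higher (2.47 ± 0.34 (adjusted p = 0.000460)).

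The endoplasmic reticulum chaperone and unfolded protein response list fell: 17 of 27 members were lower and 0 higher (20 and 0 when adjusted over the list alone; camera adjusted p = 1.27e-12, against adjusted p = 0.427 with an estimated correlation). Hyou1 was at -1.62 ± 0.28 (adjusted p = 0.00194) and Manf, a secreted stress factor, at -1.45 ± 0.30 (adjusted p = 0.00657). Of 21 NRF2 and oxidative stress genes 9 rose and 1 fell (9 and 1 when adjusted over the list alone; camera adjusted p = 0.000431, against adjusted p = 0.427 with an estimated correlation). Nqo1, a quinone reductase, rose by 1.70 ± 0.28 (adjusted p = 0.00118). In the list of ATF4 and the amino acid response, 3 of 25 rose and 2 fell (5 and 2 when adjusted over the list alone). The stress hormone gene Gdf15 was at 2.87 ± 0.51 (adjusted p = 0.00302). Hepatokines held 3 higher and 6 lower of 23 (5 and 9 when adjusted over the list alone), insulin and FOXO1 targets 1 higher and 1 lower of 17 (1 and 2), and circadian clock genes 0 higher and 1 lower of 21, the same counts adjusted over the list alone.

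Parts of the injury, matrix and inflammatory lists rose after the high-fat diet. Of 22 oncofetal and hepatocyte injury genes 9 rose (14 when adjusted over the list alone; camera adjusted p = 2.97e-06, against adjusted p = 0.448 with an estimated correlation). Among them was the keratin gene Krt8 at 1.26 ± 0.18 (adjusted p = 0.000457). Of 32 fibrosis and matrix genes 13 rose (18 when adjusted over the list alone; camera adjusted p = 4.60e-08, against adjusted p = 0.580 with an estimated correlation). The macrophage elastase gene Mmp12 was at 4.28 ± 0.89 (adjusted p = 0.00870). Col1a1, a fibrillar collagen, was at 36.9 ± 8.35 against 11.1 ± 7.53 CPM and missed the threshold (1.73 ± 0.54 (adjusted p = 0.0561)). It passed with DESeq2 (adjusted p = 0.0151) and without control replicate 2 (adjusted p = 0.0224) or high-fat replicate 1 (adjusted p = 0.0496). Of 26 cell cycle genes 6 rose (9 when adjusted over the list alone; camera adjusted p = 0.000358, against adjusted p = 0.711 with an estimated correlation). Of 24 inflammatory cytokines and chemokines 4 rose (4 when adjusted over the list alone; camera adjusted p = 7.02e-05, against adjusted p = 0.703 with an estimated correlation). Markers of monocyte-derived and lipid-associated macrophages held 4 higher and 1 lower of 21 (12 and 1 when adjusted over the list alone; camera adjusted p = 0.00101, against adjusted p = 0.739 with an estimated correlation). Gpnmb rose by 3.86 ± 0.89 (adjusted p = 0.0163). Fabp5, a fatty acid binding protein also made by other cells, fell (-2.75 ± 0.35 (adjusted p = 0.000383)). Trem2, a receptor of lipid-associated macrophages, missed the threshold (1.93 ± 0.70 (adjusted p = 0.0909)) but passed with DESeq2 (adjusted p = 0.0327). The call on Gpnmb was lost without control replicate 3, 4 or 5 (adjusted p from 0.0503 to 0.0552). Of 13 stellate cell and fibroblast markers 4 rose (4 when adjusted over the list alone; camera adjusted p = 0.00113, against adjusted p = 0.448 with an estimated correlation). The pericyte gene Rgs5 was at 1.14 ± 0.19 (adjusted p = 0.00122). Of 27 acute phase genes 8 rose (11 rose and 2 fell when adjusted over the list alone), not including the serum amyloid gene Saa1 (1.63 ± 0.72 (adjusted p = 0.163)). The interferon response held 1 higher of 26 (5 when adjusted over the list alone). Hepatocyte markers held 1 lower and 0 higher of 12 (3 and 0 when adjusted over the list alone; camera adjusted p = 0.00475, against adjusted p = 0.603 with an estimated correlation).

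Some sex-biased liver genes changed in these male livers. Of 26 tested female-biased genes, 13 rose and 2 fell (15 and 3 when adjusted over the list alone; camera adjusted p = 1.83e-05, against adjusted p = 0.489 with an estimated correlation). Cyp2b9 and Cyp2b13 were among the 13, and the list's median log2 fold change was 1.77, also with Cyp2b13 at its bound. Of 25 male-biased genes 4 fell and 0 rose (14 and 0 when adjusted over the list alone; camera adjusted p = 1.98e-07, against adjusted p = 0.580 with an estimated correlation), Moxd1 the most strongly. Of the 26 female-biased genes, 5 are also in the lists of PPAR-alpha or of xenobiotic targets. Xenobiotic P450 enzymes and CAR/PXR targets held 5 higher and 1 lower of 21 (5 and 2 when adjusted over the list alone). Cyp2b9, Cyp2b13, Cyp4a10 and Cyp4a14 belong to families of similar genes, and how reads shared between copies were counted is not given in the sources used here, so the values of single family members are uncertain.

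Ketogenic and control livers were compared next. After the 89.9% fat diet 32 of 36 oxidation genes, 4 of 6 ketone genes and 15 of 24 lipid droplet genes were higher than in controls. Of 25 genes of de novo lipogenesis 20 were lower, together with some genes of sugar and amino acid breakdown. These list calls are also lost with an estimated correlation (adjusted p from 0.0515 to 0.703). Cidec was at 93.4 ± 7.19 CPM against 2.99 ± 1.53 in controls, and Fasn at 455 ± 387 against 4032 ± 1114 CPM. Acly, which makes cytosolic acetyl-CoA for fat synthesis, went from 1273 ± 251 to 189.8 ± 42.0 CPM. In edgeR's test 1093 genes rose and 673 fell, 563 and 188 of them by at least 2-fold. Library totals in place of TMM shifted the median gene by 0.177 on the log2 scale and gave 1826 higher and 368 lower. Of all tested genes, 12.5% had no overlap between the CPM values of both groups, where chance gives 1.59%. The count fell to 1156 without control replicate 3, 1056 without control replicate 4 and 1124 without control replicate 5; without ketogenic replicate 5 it was 1766, and 1476 of the main calls were kept.

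Among the genes with the largest changes after the ketogenic diet were again cytochrome P450 enzymes. Cyp4a14 rose from 2.74 ± 1.89 to 714 ± 393 CPM (log2 fold change 8.03 ± 0.93 (SE), adjusted p = 0.000171). Its relative Cyp4a10 rose from 8.76 ± 8.32 to 453 ± 167 CPM (log2 fold change 5.70 ± 0.65 (SE), adjusted p = 0.000132) and Cyp2b9 from 0.632 ± 0.547 to 110.0 ± 79.0 CPM (log2 fold change 7.43 ± 0.87 (SE), adjusted p = 0.000196). Sptlc3, a subunit of the enzyme that starts sphingolipid synthesis, was at 0 counts in controls and 2.72 ± 2.11 CPM after the ketogenic diet, at least 63.2-fold higher against the floor of 3 counts over the control group (adjusted p = 0.0309). Sprr1a was at least 25.5-fold higher by the same floor (adjusted p = 0.0446), and Mab21l3 had 141 counts against 1 in controls, a ratio of 92.8 with a 95% counting interval of 16.4 to 3690. Moxd1 fell from 39.5 ± 42.3 to 0.0342 ± 0.0379 CPM (log2 fold change -9.90 ± 1.51 (SE), adjusted p = 0.00127). Tff3 fell from 26.6 ± 23.2 to 0.448 ± 0.287 CPM (log2 fold change -5.87 ± 0.73 (SE), adjusted p = 0.000219) and Chrna4, a nicotinic receptor subunit, from 11.4 ± 5.46 to 0.205 ± 0.242 CPM (log2 fold change -5.64 ± 0.66 (SE), adjusted p = 0.000108). Adgrf1 had a log2 fold change of -5.08 ± 0.51 (adjusted p = 2.55e-05), Pnpla3 of -4.87 ± 1.02 (adjusted p = 0.00890) and Nat8f7 of -4.72 ± 0.62 (adjusted p = 0.000175). The call on Sptlc3 was lost without any 1 of 6 libraries (control replicates 3, 4 and 5 and ketogenic replicates 1, 2 and 4; adjusted p from 0.0507 to 0.0700). The call on Sprr1a was lost without any 1 of 7 (control replicates 2, 3, 4 and 5 and ketogenic replicates 1, 2 and 5; adjusted p from 0.0588 to 0.0911). Without ketogenic replicate 5 the log2 fold change was -6.70 for Chrna4, -8.24 for Pnpla3, -6.42 for Nat8f7 and 5.16 for Mab21l3, and the bound for Sprr1a was 10.4-fold. Without control replicate 5 it was 6.58 for Cyp4a10, and Mab21l3, then at 0 in controls, was at least 23.7-fold higher. Without control replicate 4 the log2 fold change was -9.23 for Moxd1, and without control replicate 2 -5.09 for Tff3.

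The lipogenic program fell after the ketogenic diet. Of its 25 genes 20 fell and 0 rose (21 and 0 when adjusted over the list alone; camera adjusted p = 8.38e-20, against adjusted p = 0.0515 with an estimated correlation). Pklr fell by 2.20 on the log2 scale (adjusted p = 6.02e-06). Acly (-2.75 ± 0.33 (adjusted p = 0.000111)), Fasn (-3.15 ± 0.54 (adjusted p = 0.00176)) and Srebf1 (-2.09 ± 0.31 (adjusted p = 0.000520)) were lower. Scd1 did not pass (-1.81 ± 1.85 (adjusted p = 0.558)), with 4183 ± 9301 CPM against 14652 ± 4549.6: ketogenic replicate 5 had 20820 CPM and the other 4 ketogenic libraries 9.60 to 56.2 CPM. Without ketogenic replicate 5 the log2 fold change of Scd1 was -9.35 (adjusted p = 5.45e-06) and that of Fasn -3.85 (adjusted p = 5.58e-05).

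Fat oxidation, ketone and storage genes rose as on the high-fat diet. Of 36 PPAR-alpha targets and oxidation genes 32 rose and 0 fell (34 and 0 when adjusted over the list alone; camera adjusted p = 5.97e-33, against adjusted p = 0.0515 with an estimated correlation). Vnn1 was at 3.90 ± 0.31 (adjusted p = 6.02e-06) and Cpt1a at 0.77 ± 0.19 (adjusted p = 0.0137). Of 6 ketogenesis genes 4 rose (5 when adjusted over the list alone; camera adjusted p = 6.66e-06, against adjusted p = 0.0653 with an estimated correlation). Among them were Acat1 (1.31 ± 0.16 (adjusted p = 0.000127)) and Bdh1, the hydroxybutyrate dehydrogenase (1.25 ± 0.18 (adjusted p = 0.000384)). Of 24 lipid droplet and uptake genes 15 rose and 1 fell (17 and 1 when adjusted over the list alone; camera adjusted p = 2.84e-14, against adjusted p = 0.0515 with an estimated correlation). Cidec was at 4.96 ± 0.41 (adjusted p = 1.15e-05), Cidea at 5.53 ± 0.77 (adjusted p = 0.000578), Cd36 at 2.99 ± 0.29 (adjusted p = 2.10e-05) and Plin2 at 1.63 ± 0.21 (adjusted p = 0.000170). Fgf21 rose by 2.82 ± 0.37 (adjusted p = 0.000168) and Pdk4 by 1.49 ± 0.45 (adjusted p = 0.0444). The call on Pdk4 was lost without any 1 of 7 libraries (control replicates 3, 4 and 5 and ketogenic replicates 1, 2, 4 and 5; adjusted p from 0.0515 to 0.122) and with the library number set as a covariate (adjusted p = 0.0598).

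Parts of the sugar and amino acid lists fell. Of 20 genes of glycolysis and fructose metabolism 9 fell and 0 rose (9 and 0 when adjusted over the list alone; camera adjusted p = 1.02e-07, against adjusted p = 0.0515 with an estimated correlation). Of 16 genes of gluconeogenesis and glycogen 3 rose and 6 fell (3 and 6 when adjusted over the list alone). Pygl, the liver glycogen phosphorylase, was at -0.93 ± 0.12 (adjusted p = 0.000188) while Pck1 did not pass (0.48 ± 0.37 (adjusted p = 0.417)). Of 37 genes of amino acid breakdown and the urea cycle 3 rose and 11 fell (3 and 11 when adjusted over the list alone; camera adjusted p = 0.000337, against adjusted p = 0.703 with an estimated correlation). Among those that fell were the urea cycle genes Cps1 (-1.23 ± 0.21 (adjusted p = 0.00142)) and Ass1 (-1.09 ± 0.18 (adjusted p = 0.00108)) and the glutaminase gene Gls2 (-1.10 ± 0.16 (adjusted p = 0.000434)). Of 15 periportal hepatocyte genes, 4 fell (4 when adjusted over the list alone; camera adjusted p = 0.00139, against adjusted p = 0.430 with an estimated correlation), of which Cps1 and Gls2 are also in the amino acid list. Of 16 pericentral genes 1 rose (1 when adjusted over the list alone). Cholesterol synthesis and SREBP2 targets held 1 higher and 3 lower of 25 (1 and 6 when adjusted over the list alone), the 1 being Hmgcs1, the cytosolic HMG-CoA synthase (1.73 ± 0.33 (adjusted p = 0.00350)). Bile acid genes held 5 higher and 2 lower of 24 (5 and 5 when adjusted over the list alone). Abcb4 was at 1.21 ± 0.17 (adjusted p = 0.000270) and Abcc3 at 1.89 ± 0.30 (adjusted p = 0.000743). Cyp7a1 did not pass, at -0.24 ± 0.49 (adjusted p = 0.783). Cholesterol efflux genes held 1 higher and 3 lower of 24, the same counts adjusted over the list alone, with Apoa4 at 1.91 ± 0.34 (adjusted p = 0.00171).

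Parts of the oxidative stress, interferon, injury and matrix lists rose after the ketogenic diet. Of 27 chaperone and unfolded protein response genes 3 fell (3 when adjusted over the list alone; camera adjusted p = 0.00328, against adjusted p = 0.782 with an estimated correlation, and 0.214 at the preset correlation without ketogenic replicate 5). NRF2 and oxidative stress genes held 8 higher of 21 (10 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.000233, against adjusted p = 0.427 with an estimated correlation). Nqo1 was at 1.56 ± 0.27 (adjusted p = 0.00155). The ATF4 list held 3 higher of 25 (3 when adjusted over the list alone). Gdf15 was at 2.39 ± 0.50 (adjusted p = 0.00749). Of 26 interferon response genes 7 rose (13 when adjusted over the list alone; camera adjusted p = 0.000154, against adjusted p = 0.448 with an estimated correlation). Ifi44 was at 1.27 ± 0.24 (adjusted p = 0.00310). Of 22 injury genes 9 rose (11 when adjusted over the list alone; camera adjusted p = 2.02e-05, against adjusted p = 0.489 with an estimated correlation). Krt8 was at 1.21 ± 0.18 (adjusted p = 0.000388). Of 32 matrix genes 16 rose (26 when adjusted over the list alone; camera adjusted p = 4.60e-08, against adjusted p = 0.580 with an estimated correlation). Mmp12 was at 4.94 ± 0.90 (adjusted p = 0.00354). Of 26 cell cycle genes 8 rose and 1 fell (17 and 1 when adjusted over the list alone; camera adjusted p = 6.25e-05, against adjusted p = 0.703 with an estimated correlation). The cyclin gene Ccnd1 was at 1.23 ± 0.23 (adjusted p = 0.00246). Leaving out ketogenic replicate 5 moved the log2 fold change of Mmp12 to 4.02. Col1a1 passed (2.02 ± 0.55 (adjusted p = 0.0299)), and its call was lost without any 1 of 6 libraries (control replicates 3, 4 and 5 and ketogenic replicates 1, 2 and 5; adjusted p from 0.0532 to 0.0873).

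Among cell types, lipid-associated macrophage markers held 6 higher and 1 lower of 21 (11 and 1 when adjusted over the list alone; camera adjusted p = 0.0122, against adjusted p = 0.860 with an estimated correlation, and 0.0503 at the preset correlation without ketogenic replicate 5). Trem2 went from 1.29 ± 0.257 to 8.12 ± 9.51 CPM (log2 fold change 2.66 ± 0.71 (SE), adjusted p = 0.0262), with 24.9 CPM in ketogenic replicate 5 and 1.61 to 6.37 in the other ketogenic libraries. Leaving that library out, the log2 fold change was 1.59 (adjusted p = 0.0238), and without control replicate 3, 4 or 5 the call was lost (adjusted p from 0.0725 to 0.0802). Gpnmb rose by 4.95 ± 0.92 (adjusted p = 0.00438) and by 3.84 without ketogenic replicate 5, and Fabp5 fell (-2.87 ± 0.36 (adjusted p = 0.000175)). Resident Kupffer cell markers held 0 higher and 2 lower of 16 (0 and 2 when adjusted over the list alone). Hepatocyte markers held 0 higher and 3 lower of 12 (0 and 10 when adjusted over the list alone; camera adjusted p = 4.93e-05, against adjusted p = 0.430 with an estimated correlation). Sinusoidal endothelial markers held 0 higher and 5 lower of 15 (0 and 5 when adjusted over the list alone; camera adjusted p = 0.00164, against adjusted p = 0.595 with an estimated correlation), against 1 higher and 3 lower (1 and 3) in high-fat livers. Adipocyte markers, of which Cidea and 2 others are shared with the lipid droplet list, held 4 higher of 9 (4 higher and 1 lower when adjusted over the list alone), and 3 of 9 (5) in high-fat livers. Inflammatory cytokines held 3 higher of 24 (3 when adjusted over the list alone; camera adjusted p = 0.00169, against adjusted p = 0.739 with an estimated correlation, and 0.106 at the preset correlation without ketogenic replicate 5). Acute phase genes held 6 higher and 2 lower of 27 (9 and 6 when adjusted over the list alone), not including Saa1 (1.99 ± 0.73 (adjusted p = 0.0975); adjusted p = 0.0306 with DESeq2). Stellate cell markers held 1 higher of 13 (0 when adjusted over the list alone).

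Female-biased genes held 10 higher and 2 lower of 26 (13 and 3 when adjusted over the list alone; camera adjusted p = 0.0102, against adjusted p = 0.711 with an estimated correlation). Male-biased genes held 0 higher and 3 lower of 25 (0 and 7 when adjusted over the list alone; camera adjusted p = 0.000233, against adjusted p = 0.703 with an estimated correlation). Xenobiotic targets held 3 higher and 2 lower of 21 (4 and 2 when adjusted over the list alone): Nr1i3, the gene of the receptor CAR, rose (1.44 ± 0.21 (adjusted p = 0.000377)) and Cyp2c29 fell (-1.82 ± 0.29 (adjusted p = 0.000705)). Hepatokines held 4 higher and 5 lower of 23 (5 and 8 when adjusted over the list alone), insulin and FOXO1 targets 1 higher and 1 lower of 17, clock genes 0 higher and 1 lower of 21 and mitochondrially encoded mRNAs 0 higher and 1 lower of 13, the same counts adjusted over the list alone for these 3 lists. Of the 122 tested members of 10 further lists (nuclear OXPHOS subunits, neutrophil, T and NK cell, B and plasma cell, dendritic cell, cholangiocyte, erythroid, pancreatic acinar, skeletal muscle and mesothelium markers), 0 passed edgeR's test in either comparison with control. Of the same 122, 10 in high-fat and 13 in ketogenic livers had an unadjusted p below 0.05, DESeq2 called 4 and 3, and limma-voom 10 and 5. Adjusted over the list alone, 2 and 3 neutrophil markers were lower and 0 members of the other 9 lists passed. Among these lists camera called dendritic cell markers higher in high-fat livers (camera adjusted p = 0.0239, against adjusted p = 0.739 with an estimated correlation), a call lost without control replicate 3 (adjusted p = 0.0548). Acinar markers were called higher there (camera adjusted p = 0.0122, against adjusted p = 0.860 with an estimated correlation), although the median log2 fold change of the members was -0.385. That call was lost with the library number set as a covariate (adjusted p = 0.915) and without high-fat replicate 1 or control replicate 3 or 4 (adjusted p from 0.0651 to 0.653). In ketogenic livers camera called acinar markers lower (camera adjusted p = 0.000358, against adjusted p = 0.712 with an estimated correlation) and erythroid markers lower (camera adjusted p = 0.0306, against adjusted p = 0.703 with an estimated correlation), the erythroid call being lost without control replicate 2 (adjusted p = 0.0987) or ketogenic replicate 5 (adjusted p = 0.201). Of the lists with members past the threshold, camera also called adipocyte markers higher in high-fat livers (camera adjusted p = 0.0102, against adjusted p = 0.526 with an estimated correlation), lost without control replicate 5 (adjusted p = 0.0711). Acute phase genes were called higher there (camera adjusted p = 0.0440, against adjusted p = 0.860 with an estimated correlation), lost without control replicate 2, 3 or 5 or high-fat replicate 1, 4 or 5 (adjusted p from 0.0521 to 0.163). Clock genes were called lower there (camera adjusted p = 0.0348, against adjusted p = 0.676 with an estimated correlation), lost without control replicate 3, 4 or 5 or high-fat replicate 4 or 5 (adjusted p from 0.0573 to 0.105). Cholesterol efflux genes were called lower in ketogenic livers (camera adjusted p = 0.0235, against adjusted p = 0.448 with an estimated correlation), lost without control replicate 5 (adjusted p = 0.0790). In high-fat livers 0 of 16 Kupffer markers and 0 of 13 mitochondrial mRNAs passed either way (2 and 0 at an unadjusted p below 0.05, 1 and 0 by DESeq2, 7 and 0 by limma-voom). In the same livers 1 periportal gene of 15 rose and 1 fell (2 and 1 when adjusted over the list alone) and 1 pericentral gene of 16 rose, as it did adjusted over the list alone. Intestinal and gallbladder markers held 1 higher of 4 in high-fat livers (1 higher and 2 lower when adjusted over the list alone) and 2 higher and 1 lower in ketogenic ones (2 and 2). The only kidney marker tested of 11 was not called in high-fat livers by edgeR over all genes (unadjusted p below 0.05, called by DESeq2 and limma-voom and when adjusted over the list alone) and was lower in ketogenic ones. Of 10 pancreatic islet markers 0 were abundant enough to test.

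**Figure D2:**
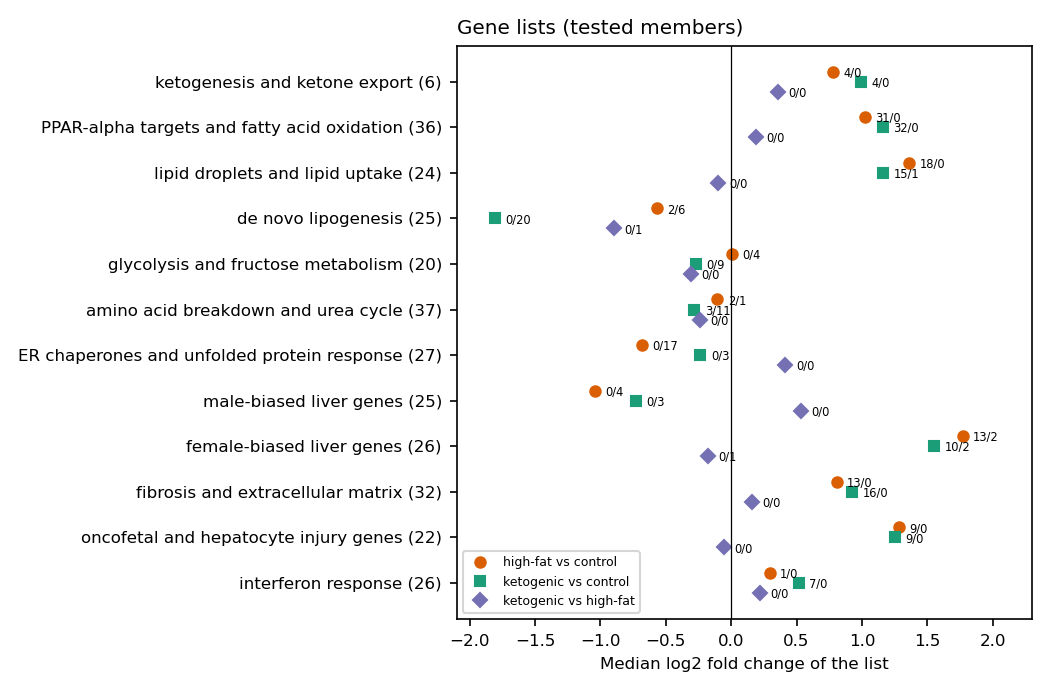
Median log2 fold change of 12 gene lists in each comparison (x axis), with the number of tested members in brackets; circles, squares and diamonds mark the 3 comparisons, and the label beside each gives the members higher and lower past edgeR's threshold. De novo lipogenesis lies at -0.57 in high-fat and -1.81 in ketogenic livers against control, with 2 higher and 6 lower and with 0 higher and 20 lower members.

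Ketogenic and high-fat livers were compared directly to ask how the diet with 89.9% fat differed from that with 60% fat. Few single genes passed edgeR's test: 1 rose and 8 fell of 14627, and 1273 had an unadjusted p below 0.05. The other tools called more. Cyp17a1 (ENSMUSG00000003555), a steroid hydroxylase, was at 7.84 ± 4.12 CPM in ketogenic and 71.0 ± 23.2 in high-fat livers (log2 fold change -3.17 ± 0.33 (SE), adjusted p = 0.00201). The fatty acid desaturase gene Fads1 (ENSMUSG00000010663) was at 471 ± 45.2 against 876 ± 133 CPM (log2 fold change -0.90 ± 0.12 (SE), adjusted p = 0.0149). Genes of lipogenesis and of glycolysis were lower as groups in ketogenic livers. DESeq2 called 62 higher and 111 lower genes and limma-voom 213 and 214. Without ketogenic replicate 5 edgeR called 135 higher and 180 lower genes, with all 9 kept. It called 1 without high-fat replicate 2, ketogenic replicate 1 or ketogenic replicate 4, 2 without ketogenic replicate 2, and 5 without high-fat replicate 4 or 5.

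The other genes lower in ketogenic livers were Cyb5r3, a cytochrome b5 reductase (-0.76 ± 0.11 (adjusted p = 0.0223)), the lectin gene Mbl2 (-1.01 ± 0.17 (adjusted p = 0.0322)), Chrna4 (-3.96 ± 0.64 (adjusted p = 0.0322)) and Lrtm1 (-2.82 ± 0.43 (adjusted p = 0.0224)). The 3 remaining calls, named after their values were seen, were Prob1 at -0.63 ± 0.10 (adjusted p = 0.0307) and 1810008I18Rik at -1.09 ± 0.17 (adjusted p = 0.0224), both lower, and Gm15638 at 1.10 ± 0.17 (adjusted p = 0.0223), higher. Of all tested genes, 1.76% had no overlap between both groups, where chance gives 0.794%. Over the 10 fits that leave out 1 fat-fed library, Cyp17a1 was called in 10, Fads1 in 7, Cyb5r3 and Gm15638 in 5, Lrtm1 and 1810008I18Rik in 4, Mbl2 in 3 and Chrna4 and Prob1 in 2. The highest adjusted p was 0.0178 for Cyp17a1 and 0.176 for Chrna4. Fads1 was lost without high-fat replicate 2 and ketogenic replicates 1 and 4, Cyb5r3 without these 3, high-fat replicate 4 and ketogenic replicate 2, and Lrtm1 without these 5 and ketogenic replicate 3. Mbl2 was lost without high-fat replicates 1, 2, 4 and 5 and ketogenic replicates 1, 2 and 4. Chrna4 was lost without high-fat replicates 1, 2, 3 and 5 and ketogenic replicates 1, 2, 3 and 4. Chrna4 and Mbl2 were also lost with the library number set as a covariate (adjusted p = 0.0580 for both), and without ketogenic replicate 5 Chrna4 was at -5.00.

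Lipogenic transcripts were lower in ketogenic than in high-fat livers. Of 25 genes of de novo lipogenesis 1 fell, Fads1 (19 when adjusted over the list alone), and the list was lower with both settings of the test (camera adjusted p = 6.78e-30, and adjusted p = 0.0268 with an estimated correlation). Its median log2 fold change was -0.90. Fasn (-1.77 ± 0.50 (adjusted p = 0.236)), Scd1 (-1.38 ± 1.76 (adjusted p = 0.917)) and Srebf1 (-0.80 ± 0.29 (adjusted p = 0.398)) did not pass one by one. Without ketogenic replicate 5, 14 of the 25 fell, with Scd1 at -8.90 (adjusted p = 5.32e-05) and Fasn at -2.46 (adjusted p = 0.00689). Glycolysis and fructose metabolism was also lower with both settings (camera adjusted p = 8.48e-15, and adjusted p = 0.0249 with an estimated correlation), with 0 of 20 members past edgeR's test over all genes (12 lower when adjusted over the list alone, 13 at an unadjusted p below 0.05, 10 by DESeq2 and 10 by limma-voom).

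Over 44 lists, all but those of lipogenesis and female-biased genes among the 46 with a tested member, 0 of 760 distinct members passed edgeR's test between the fat-rich diets; 127 had an unadjusted p below 0.05, DESeq2 called 40 and limma-voom 82. Adjusted over the list alone, 14 of 27 chaperone genes were higher (camera adjusted p = 1.75e-12, against adjusted p = 0.427 with an estimated correlation). On that basis 2 of 26 interferon response genes were higher (camera adjusted p = 6.67e-05, against adjusted p = 0.448 with an estimated correlation). Also adjusted over the list alone, 4 of 16 genes of gluconeogenesis and glycogen (camera adjusted p = 6.31e-05, against adjusted p = 0.213 with an estimated correlation), 7 of 37 of amino acid breakdown (camera adjusted p = 1.44e-08, against adjusted p = 0.489 with an estimated correlation) and 6 of 8 erythroid markers (camera adjusted p = 8.48e-07, against adjusted p = 0.333 with an estimated correlation) were lower. Of 15 periportal genes 4 were lower and 1 higher (camera adjusted p = 1.51e-05, against adjusted p = 0.213 with an estimated correlation). The erythroid gene Hbb-bs was at 168 ± 67.3 against 486 ± 288 CPM (-1.54 ± 0.37 (adjusted p = 0.154); adjusted p = 0.0327 with DESeq2). In smaller numbers, 2 of 6 ketogenesis genes, 1 clock gene, 1 insulin and FOXO1 target and 1 hepatokine were higher, and 1 cholesterol efflux gene, 2 stellate cell markers and 2 hepatokines lower, adjusted over the list alone. At the preset correlation camera also called Kupffer cell markers lower (camera adjusted p = 2.01e-05, against adjusted p = 0.489 with an estimated correlation) and sinusoidal endothelial markers lower (camera adjusted p = 0.000795, against adjusted p = 0.580 with an estimated correlation). PPAR-alpha targets were called higher (camera adjusted p = 0.00206, against adjusted p = 0.703 with an estimated correlation), as were ketogenesis genes (camera adjusted p = 0.00760, against adjusted p = 0.427 with an estimated correlation), both lost without high-fat replicate 1 (adjusted p = 0.0917 and 0.0516). Male-biased genes were called higher (camera adjusted p = 0.0197, against adjusted p = 0.860 with an estimated correlation), lost without high-fat replicate 2, 3 or 5 or ketogenic replicate 3 or 4 (adjusted p from 0.0585 to 0.582). Lower by camera were acute phase genes (camera adjusted p = 0.00170, against adjusted p = 0.703 with an estimated correlation), lost without high-fat replicate 5 or ketogenic replicate 4 (adjusted p = 0.0732 and 0.109). So were cholesterol efflux genes (camera adjusted p = 0.0180, against adjusted p = 0.448 with an estimated correlation), lost without high-fat replicate 1 or ketogenic replicate 1 (adjusted p = 0.0717 and 0.0807). Dendritic cell markers were called lower (camera adjusted p = 0.00715, against adjusted p = 0.703 with an estimated correlation), lost without ketogenic replicate 2, 3 or 4 (adjusted p from 0.0583 to 0.0829). Stellate cell markers were called lower (camera adjusted p = 0.0135, against adjusted p = 0.595 with an estimated correlation), lost without high-fat replicate 4 or ketogenic replicate 2 or 3 (adjusted p from 0.0530 to 0.0660). Hepatocyte markers were called lower (camera adjusted p = 0.0297, against adjusted p = 0.703 with an estimated correlation), lost without high-fat replicate 1, 4 or 5 or ketogenic replicate 1 or 5 (adjusted p from 0.0672 to 0.476). Of 26 female-biased genes 1 fell, Cyp17a1 (1 when adjusted over the list alone; camera adjusted p = 0.00138, against adjusted p = 0.686 with an estimated correlation), and the list call was lost without ketogenic replicate 4 (adjusted p = 0.0583). Cpt1a, Fgf21 and Pdk4 did not pass: Cpt1a was at 0.04 ± 0.17 (adjusted p = 0.981), Fgf21 at 0.36 ± 0.30 (adjusted p = 0.811) and Pdk4 at -0.33 ± 0.39 (adjusted p = 0.908). Genes of lipid storage did not pass either: Plin2 at -0.21 ± 0.19 (adjusted p = 0.843), Cidec at -0.05 ± 0.31 (adjusted p = 0.983), Cidea at -0.70 ± 0.51 (adjusted p = 0.781) and Cd36 at -0.13 ± 0.25 (adjusted p = 0.952). Pck1 (0.08 ± 0.35 (adjusted p = 0.980)), Cyp7a1 (0.34 ± 0.46 (adjusted p = 0.927)), Cyp2b9 (-0.01 ± 0.54 (adjusted p = 0.997)), Trem2 (0.73 ± 0.59 (adjusted p = 0.809)), Col1a1 (0.29 ± 0.48 (adjusted p = 0.947)) and Saa1 (0.35 ± 0.65 (adjusted p = 0.951)) did not pass, which does not show that they are equal. Pancreatic acinar markers, from tissue beside the liver, were lower in ketogenic libraries as a list (camera adjusted p = 8.14e-14, against adjusted p = 0.427 with an estimated correlation). Of the 17 members 0 passed edgeR's test either way. At an unadjusted p below 0.05 there were 2, and by DESeq2 or limma-voom 0.

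**Figure D3:**
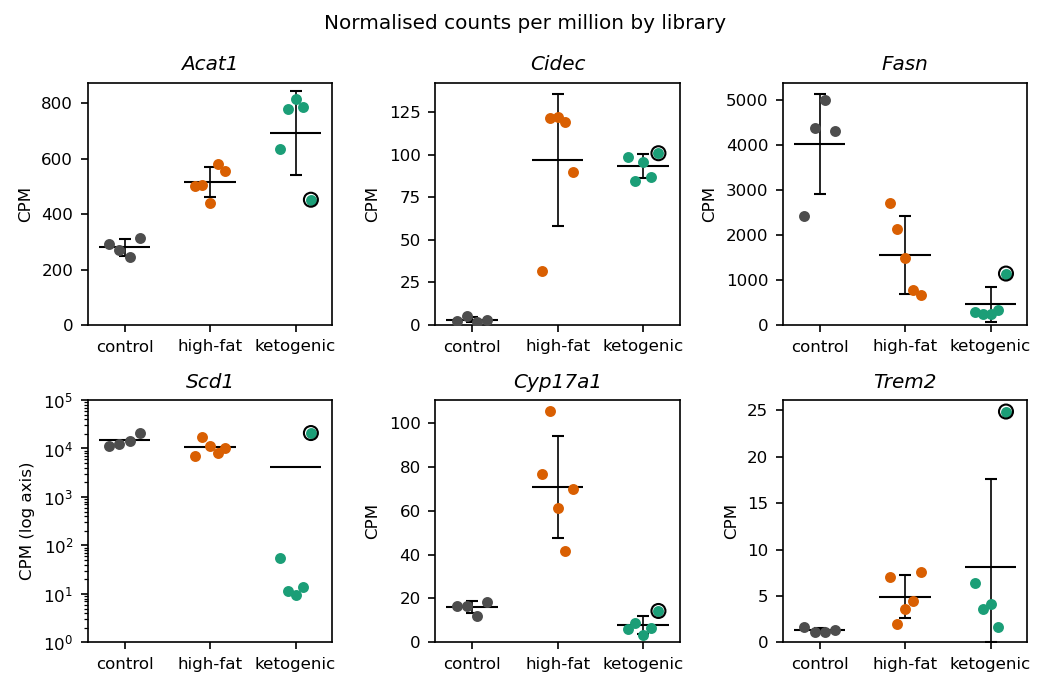
CPM of 6 genes in each of the 14 libraries (y axis; log axis for Scd1) by diet (x axis); points are libraries, horizontal lines means and vertical bars SD, which stop at 0 and are not drawn for Scd1, and the ringed point is ketogenic replicate 5. In Scd1 that library lies at 20820 CPM and the other ketogenic libraries at 9.60 to 56.2 CPM.

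Both fat-rich diets were also compared through their changes against the same controls. Genes that rose on one diet tended to be higher on the other: over the 14627 genes the log2 fold changes had a Pearson r of 0.872 and a Spearman rho of 0.820, across genes, which are not independent replicates. Of the genes that passed in edgeR's test, 758 rose on both diets, where independent lists would share 75.9, and 348 fell on both, where they would share 33.7; 0 passed in opposite directions. Because the control libraries are shared, all 14 libraries were simulated 20 times without a diet effect, with simulated controls shared by both comparisons. These gave an r of 0.571 ± 0.014 (SD), a covariance of 0.0578 against the observed 0.432, and so a difference of 0.374. Each gene was drawn from its mean over all libraries and its fitted spread, so deviations particular to the real controls are not in these values. With the 4 controls split so that each diet met its own 2, over 6 assignments r ran from 0.593 to 0.705 and the covariance from 0.338 to 0.373, with 106 to 161 genes higher on both and 36 to 52 lower on both. With ketogenic replicate 5 left out r was 0.779.

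**Figure D4:**
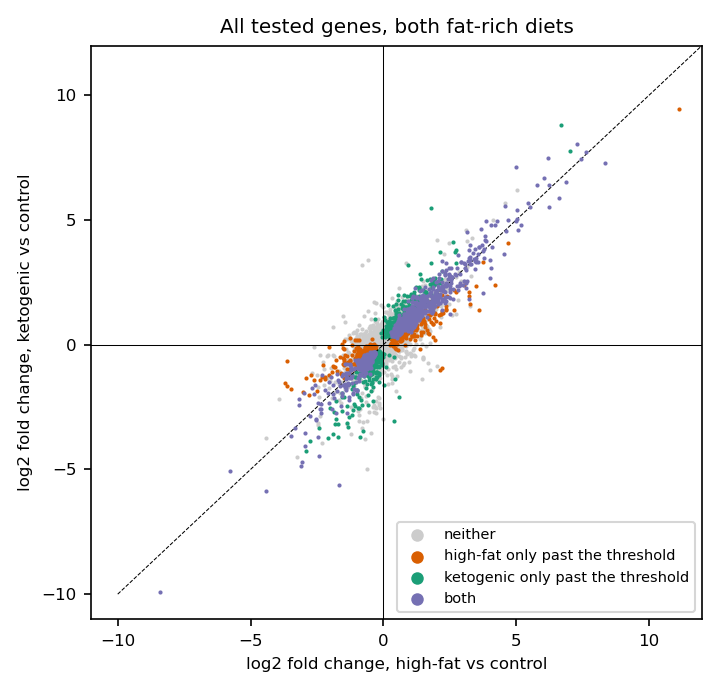
Log2 fold change of each tested gene against control on the high-fat diet (x axis) and on the ketogenic diet (y axis); colours show in which comparison a gene passed edgeR's threshold and the dashed line marks equal change. Of the genes past the threshold, 758 lie in the upper right and 348 in the lower left for both diets.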

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

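The tests of technical explanations below were chosen after the results they bear on were seen; the splits of the libraries and the marker lists were fixed before the data were examined, but what each would show was written down only afterwards. The test of mixed RNA and the test of the acinar ratio were also revised after a first version had been run.

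Among the genes named, single libraries lay far from the rest of their group (CPM) in 19 cases, and in 2 more for the acinar share of counts. Over 225 groups tested, 21 gaps were found where chance gives 11.2. Chance flags about 1 in 20 groups. Ketogenic replicate 5 held 8 of the 21 and high-fat replicate 1 held 7. Ketogenic replicate 5 was at 3.30 for Pnpla3 (others 0 to 0.204), 0.439 for Nat8f7 (0 to 0.102), 1144 for Fasn (253 to 343), 20820 for Scd1 (9.60 to 56.2) and 226 for Gpi1 (181 to 190), all higher, and at 215 for Bdh1 (371 to 452), 222 for Nr1i3 (390 to 452) and 106 for Hmgcs1 (289 to 424), all lower. High-fat replicate 1 was at 0.636 for Moxd1 (others 0) and 446.5 for Gls2 (295 to 331), both higher, and at 31.6 for Cidec (89.6 to 122), 88.2 for Vnn1 (133 to 138), 186 for Abcc3 (317 to 344), 838 for Apoa4 (2421 to 2826) and 49.4 for Rgs5 (86.0 to 102), all lower. Saa1 was at 122 in high-fat replicate 2 (207 to 229), Abcc3 at 457 in ketogenic replicate 1 (240.0 to 277), Pnpla3 at 8.40 in control replicate 3 (26.1 to 29.4) and Mab21l3 at 0.0571 in control replicate 5 (others 0). Acinar transcripts were 0.199% of counts in control replicate 2 (other controls used 0.00265 to 0.0181) and 0.0425% in ketogenic replicate 2 (others 0.000853 to 0.00237). The excluded control replicate 1, which enters no comparison, held 1.897% against at most 0.199% in another control.

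Ketogenic replicate 5 stood apart from the other ketogenic livers: of the 315 genes called between the fat-rich diets without it, it lay beyond the other ketogenic libraries on the high-fat side for 287 (91.1%), and for 70 (22.2%) outside the high-fat range on the ketogenic side, where a further library like the 5 high-fat ones would do so for 16.7% before any selection of genes. On a scale from ketogenic (0) to high-fat (1) over the 100 genes that best separate the diets without it, it lay at 0.957, among the held-out high-fat libraries (0.677 to 1.06) and above the other ketogenic ones (-0.013 to 0.354), so a high-fat liver under a ketogenic label may account for it, while no high-fat library lay low enough to be its partner in a swap. High-fat RNA mixed into a ketogenic sample would need a share of 0.987 over such genes, within the 0.635 to 1.04 of held-out high-fat libraries. On these genes a mixture therefore cannot be told apart from a wrong label. Against a plain high-fat liver stand Cyp17a1 at 14.3 CPM (high-fat 41.8 to 105), Chrna4 at 0.622 (1.62 to 7.10) and Fads1 at 471.9 (760.9 to 1067), although these 3 genes were called with the library in its group, and Trem2 at 24.9 (2.01 to 7.56) and Gpnmb at 119.8 (13.04 to 24.01) CPM lay above both diets. A response of this animal to the ketogenic diet that differs from the others was not tested and stays open.

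Pancreatic acinar transcripts were seen in control replicate 1 and, at lower levels, in other libraries; Ctrb1 was at 2554 CPM there and at 1.37 to 289 in the other controls. Spill of its RNA or reads into every library with acinar transcripts is argued against by the Cela2a to Ctrb1 ratio, 0.891 in control replicate 1 but over 1.25-fold away, beyond the counting interval, in 3 of 9 libraries (ketogenic replicate 2 at 0.143, high-fat replicate 3 at 0.586 and high-fat replicate 5 at 0.481). Spill into some libraries stays open, since the ratios of 5 lay within that bound and that of high-fat replicate 2 (0.661) reached it with its counting interval, as they also could with tissue of their own. Pancreas taken with the liver is a candidate source in control replicate 1, where 7 of 10 islet markers had more counts than in any other library, among them Ins2 with 493 (at most 13 elsewhere). No biological explanation was tested.

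On the high-fat and ketogenic diets 13 and 10 of 26 female-biased liver genes rose and 2 and 2 fell, and 4 and 3 of 25 male-biased ones fell, list calls that are lost with an estimated correlation (adjusted p from 0.489 to 0.711). Female mice among the animals are argued against by Xist, with at most 3 counts in a library, and the Y-linked Ddx3y, with at least 1038. Overlap with the PPAR-alpha and CAR/PXR lists leaves most of the pattern, since 38.1% of the female-biased genes outside those lists (8 of 21) rose on the high-fat diet against 6.95% of all genes, and 33.3% (7 of 21) on the ketogenic diet against 7.47%. Outside families of similar genes, 33.3% rose on the high-fat diet (3 of 9, with 1 lower) and 22.2% on the ketogenic diet (2 of 9, with 1 lower). These small numbers cannot show whether reads shared between gene copies account for the rises within the families. That explanation stays open on both diets. An effect of the diets on sex-biased expression is a hypothesis that these data do not test apart from the diets.

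Chance as the source of the counts of changed genes is argued against in both comparisons with control. The share of the 100 splits that reached the real count was under 0.05, which does not exclude chance. For high-fat against control, 2 of 100 splits reached the real 1749 genes, the real one included, and the highest other gave 1750, with high-fat replicate 1 placed among the controls. For ketogenic against control it was 1 of 100, with 1766 genes and at most 1388 in another split. For ketogenic against high-fat it was 4 of 100, also under 0.05 with only 9 genes. A split across both diets gave 1255: high-fat replicates 1 and 4 and ketogenic replicates 2, 3 and 4 against the rest. These 5 lay nearest controls on the first component (up to 17.6, others from 31.2).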

How the results depend on the processing

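Leaving out pairs of libraries, and listing fry in place of camera, were chosen after the data were seen; the other alternatives were planned. The cause of a change in a count was not tested unless fewer samples or a stricter threshold gives it. For high-fat against control (1749 genes), an absolute log2 fold change of at least 1 left 623, adjusted p under 0.01 left 649, limma-voom called 4214, leaving out 1 library gave 934 to 2145 (lowest without control replicate 4, highest without high-fat replicate 1), and control replicate 2 and ketogenic replicate 5 out together 2670. For ketogenic against control (1766), the same settings gave 751, 767, 3432 and 1056 to 2201 (lowest without control replicate 4, highest without ketogenic replicate 3). For ketogenic against high-fat (9), they were 1 at adjusted p under 0.01, 15 with library totals, 173 with DESeq2, 427 with limma-voom, 26 with no filter, 1 with only both groups in the fit, and 1 (without high-fat replicate 2, for example) to 315 (without ketogenic replicate 5) on leaving out 1 library; control replicate 2 and ketogenic replicate 5 out together gave 396, and high-fat replicate 1 and ketogenic replicate 5 out together 636. Settings named neither here nor below stayed within 1.5 times of each count.

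The Pearson r between both diets' changes (0.872) was 0.6738 with no filter and 0.7793 (without ketogenic replicate 5) to 0.8828 (without control replicate 2) on leaving out 1 library. Of the list tests past the threshold (20, 22 and 20 in the order above), fry called 8, 10 and 4 and camera with an estimated correlation 0, 0 and 2. No label says that replicate numbers pair the libraries: over 13 same-numbered pairs the correlation of deviations ran from -0.404 to 0.418, 3 were over 0.1, and 3 of 14 libraries correlated best with their own number. With the replicate block the counts were 1380, 1297 and 15, r was 0.8354, and the pancreatic acinar list, called higher in high-fat against control (adjusted p = 0.01222), lost that call and turned its direction (adjusted p = 0.9028). Named genes changed direction past the threshold once: Cd74, a dendritic cell marker, had a log2 fold change in ketogenic against high-fat of -0.9173 without ketogenic replicate 5, and over the left-out libraries its values ran up to 0.255. Of the lists, the list cholesterol synthesis and SREBP2 targets, ketogenic vs high-fat, which had no call, turned its direction without ketogenic replicate 5 (adjusted p = 0.0003546; highest 0.7445, without high-fat replicate 2). Leaving out 1 library ended list calls in 16, 6 and 23 cases and gained them in 4, 21 and 15. Of these 15, 7 came without ketogenic replicate 5: beside the cholesterol list, macrophage markers (adjusted p = 4.025e-07), cytokines (2.23e-06), matrix (0.003196), B and plasma cell (0.006971) and injury genes (0.02202) as lower, and pericentral genes (0.002673) as higher. Over the named genes in the order above, leaving out 1 library ended a call in 137, 121 and 29 cases and gained one in 2, 3 and 6; library totals ended 4, 8 and 0 and the library number set 5, 5 and 2; the replicate block ended 11, 14 and 2 and gained 1, 0 and 0; DESeq2 ended 0 and gained 3, 1 and 3. Named genes to which DESeq2 gave no adjusted p are not in its counts, so calls on them could not be counted as ended. DESeq2 and edgeR give different fitted values for genes at 0 in a group (Cyp2b13 10.41 against 11.13). At this depth edgeR recovered 11.9%, 19.4% and 41.8% of simulated 1.5-fold changes in the 3 comparisons, so changes of that size can be missed.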

Other observations

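The tests of relations between gene lists in this part, and its genes, were chosen after their values were seen. Next in size after the genes named by rule, Ubd, a ubiquitin-like modifier, rose on both fat-rich diets (log2 fold change 4.58 ± 0.67 (adjusted p = 0.000884) on the high-fat and 5.58 ± 0.68 (adjusted p = 0.000171) on the ketogenic diet), as did Themis, known from T cell development (4.70 ± 0.60 (adjusted p = 0.000383) and 5.01 ± 0.60 (adjusted p = 0.000165)), and the glutathione transferase gene Gsta1 (5.04 ± 1.11 (adjusted p = 0.0118) and 5.42 ± 1.11 (adjusted p = 0.00720)). Gpat3, a glycerol phosphate acyltransferase, rose on both (3.72 ± 0.31 (adjusted p = 7.82e-06) and 3.98 ± 0.31 (adjusted p = 6.02e-06)), as did the transporter gene Slc22a27 (4.56 ± 0.79 (adjusted p = 0.00280) and 3.65 ± 0.78 (adjusted p = 0.00864)). Slc13a2, a dicarboxylate transporter, fell on both (-2.94 ± 0.53 (adjusted p = 0.00257) and -4.04 ± 0.57 (adjusted p = 0.000319)). The leptin receptor gene Lepr fell on both (-2.40 ± 0.48 (adjusted p = 0.00569) and -2.59 ± 0.48 (adjusted p = 0.00310)). The glucose transporter gene Slc2a4 (-3.76 ± 0.77 (adjusted p = 0.00729)), the elongase gene Elovl6 (-3.20 ± 0.62 (adjusted p = 0.00529)) and Hamp2, a relative of hepcidin (-3.45 ± 0.88 (adjusted p = 0.0246)), fell on the ketogenic diet. Without ketogenic replicate 5 the log2 fold change was -3.405 for Lepr, -5.43 for Slc2a4, -4.34 for Elovl6 and -5.35 for Hamp2. The call on Hamp2 was lost without ketogenic replicate 1 or 2 or control replicate 5 (adjusted p from 0.0513 to 0.0711). Gsta1 moved to 5.64 and 6.02 without control replicate 2, to 4.39 on the high-fat diet without high-fat replicate 5 and to 4.84 on the ketogenic diet without ketogenic replicate 1. Slc13a2 was at -4.97 on the ketogenic diet without ketogenic replicate 4. These adjusted p-values are from edgeR's quasi-likelihood test.

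Some transcripts varied widely within a diet. The clock gene Arntl ran from 0.916 to 10.4 CPM in controls, 6.36 to 19.9 in high-fat and 5.94 to 19.5 in ketogenic livers, and Dbp, a clock output gene, from 21.5 to 108, 9.15 to 42.0 and 11.1 to 43.5; high-fat replicate 5 and ketogenic replicate 5 had the highest Arntl and the lowest Dbp of their diets. Muscle actin (Acta1) reached 40.6 CPM in control replicate 3 and 44.3 in ketogenic replicate 4 and was at 0.113 in control replicate 2, and the neutrophil gene S100a8 was at 27.7 CPM in control replicate 2 and at 0.228 in control replicate 5.

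Over the 10 fat-fed livers, diet-centred means of the male-biased list were set against 6 other lists, with an exact permutation within diets (14400 permutations, two-sided) and Benjamini-Hochberg adjustment over the 6 relations. The male-biased mean was lower where cell cycle genes were higher (r = -0.95, p = 0.000764, adjusted 0.00292; rho = -0.915, p = 0.00153, adjusted 0.00897), and likewise for fibrosis genes (r = -0.838, p = 0.000972, adjusted 0.00292; rho = -0.758, p = 0.0177, adjusted 0.0354) and macrophage markers (r = -0.83, p = 0.00174, adjusted 0.00348; rho = -0.879, p = 0.00299, adjusted 0.00897). Without ketogenic replicate 5 and high-fat replicate 1, the farthest from the median, r was -0.903, -0.80 and -0.849 for these 3 lists. For de novo lipogenesis r was -0.414 (p = 0.295, adjusted 0.354; rho = -0.152, p = 0.700, adjusted 0.700; -0.298 without both), and for PPAR-alpha targets -0.0819 (p = 0.833, adjusted 0.833; rho = -0.297, p = 0.438, adjusted 0.526; -0.667 without both), neither of which passed. With only ketogenic replicate 5 left out, r was 0.0735 for lipogenesis and -0.714 for PPAR-alpha targets. In both of these lists r within the diets had opposite signs: -0.819 in ketogenic and 0.322 in high-fat livers for lipogenesis, and 0.494 and -0.894 for PPAR-alpha targets, untested with 5 libraries each. For hepatocyte markers, added after the others had been computed, r was 0.721 (p = 0.0391, adjusted 0.0587; rho = 0.588, p = 0.104, adjusted 0.156; 0.576 without both), which goes against a relation of the opposite sign. A positive r with hepatocyte markers is also what a difference in cell makeup would give, although it did not pass after adjustment. A hypothesis is that livers with more cell cycle and matrix transcripts may have less male-biased expression, which was noticed and tested on the same livers, and a difference in the cell makeup of the samples stays open beside it.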
